A study of Drosophila melanogaster with 12 samples.

How the data were processed

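Poly(A) sites were profiled in adult Drosophila melanogaster by 3'READS and 3'READS+, which select RNA fragments that end in a poly(A) tail and sequence them, so that each read marks the end of a transcript. The 12 libraries came from heads and bodies of w1118 flies, used as wild type, and of flies that carry the C4 allele of RpII215, which encodes the largest subunit of RNA polymerase II. There were 4 wild-type head, 4 wild-type body, 2 mutant head and 2 mutant body libraries. The labels do not say whether replicates are separate groups of animals, so p-values measure only the spread between these samples, which may be technical.

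Each deposited file held the count of reads at every genomic position where poly(A) tails began, by chromosome, strand and position, with no gene names and no normalization. Per the submitters' processing notes, reads had been aligned with Bowtie2 to build BDGP5. Any filter on tails, the joining of positions into sites and the protocol used for each library are not given in the sources used here. The libraries fall into 2 far-apart ranges of sample numbers. Block 1 held replicates 1 and 2 of wild-type heads and bodies, and block 2 held wild-type replicates 3 and 4 and all mutant libraries. This block was treated as a technical batch.

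The annotation used here was of a later build, BDGP6, and no coordinate was converted. Genes were therefore named only where positions with at least 200 pooled reads fell within 10 nt of annotated transcript ends at identical coordinates. This held for chromosome arm 2L up to 22258266, where 61.7% of positions matched, and for 3L up to 4919025, where 57.5% matched. After all positions were moved by a fixed distance the match fell to 0.461% and 0.113%. On the other arms it was 0.465% on 2R, 0.212% on 3R, 0.395% on chromosome 4 and 0% on X. The named regions hold 5227 genes (3244 coding), or 21.6% of the annotated genes, and 3405 of them had a position with at least 5 pooled reads. Coordinates are those of the files (BDGP5). Genes on other arms were not analysed by name.

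Positions on one strand within 24 nt of the next were joined into a site over the pooled reads of all libraries, which gave 252808 sites placed at their most used position. Chains of positions made sites wide, with a read-weighted median width of 140 nt, and 52 nt without positions under 5 pooled reads. Close alternative sites may thus be merged. Within the named regions 92.8% of reads were assigned to 1 gene on the same strand, allowing 1000 nt downstream of its end. Reads at overlapping genes (6.52%) and intergenic reads (0.722%) were left out. Strand was used throughout, so antisense genes were counted apart. How the alignment treated reads shared by near-identical copies is not given in the sources used here, so counts of such paralogs are uncertain. Among 2228 genes with a mean of at least 20 reads, 2152 were coding, of which 1330 (61.8%) used at least 2 sites and 1166 (54.2%) used at least 2 sites in the 3'UTR.

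Differential tests used edgeR 4.0.16 in R 4.3.3 with its quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Expression was tested on reads summed per gene after TMM scaling and the filterByExpr filter. 3'UTR sites were those past the last coding base of a gene. 3'UTR site choice was tested on the reads at the distal and the proximal of the 2 most used such sites, as paired columns with a term per library. Pairs needed a mean of 20 reads and a minor site of at least 5%. Upstream sites were those of a coding gene not past its last coding base, in introns, exons or coding sequence, that of the last exon included. Upstream site use compared reads at these with reads at 3'UTR sites, where each class held at least 1%. CPM were scaled by TMM over the reads of named genes. The tissue contrast used the 8 wild-type libraries with the block as a term. Genotype contrasts used the 8 libraries of block 2, with 4 groups in 1 fit, so that no difference between blocks enters them. An interaction contrast asked whether the genotype effect differs between tissues. Gene lists were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry in limma 3.58.1. DESeq2 1.42.0, limma on log2 ratios with 0.5 reads added, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were also used.

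The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be chosen later. For expression the rule took the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 10 CPM and no overlap between replicates, and up to 3 members of each list with the smallest adjusted p. For 3'UTR sites it took 8 in each direction with a change of at least 5 percentage points, and for upstream sites 5 in each direction. One result that the rule picks for 3'UTR sites is not reported here. RpII215 came first in the rule, but it lies on X outside the named regions and was not analysed here. A point allele would in any case not be checked by its 3' reads.

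Deposited totals ran from 2219693 to 9062730 reads per library, of which 291332 to 1280888 fell in named genes. An expression fold against a group with no reads was computed against a floor of 3 counts over the group, and a share of 0 is given with the upper limit that 3 counts allow. Log2 changes of site choice and upstream site use are edgeR estimates without this floor. Where a group has no reads at a site, their size is uncertain. These libraries carry no molecular identifiers in the files, so floors and limits cover counting error only. Intervals of medians and of the rank correlation are bootstraps over genes or site pairs and leave out the spread between libraries.

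The fits were tested on simulated counts with 200 changed genes, in a mix of 2-fold and 4-fold changes and, chosen after that result, in a mix of 2-, 4-, 8- and 16-fold changes. In the wider mix, 66% of 4-fold, 90% of 8-fold and 92% of 16-fold expression changes between head and body were recovered, and for 3'UTR sites 28%, 60% and 70%. For upstream sites between head and body the shares were 10%, 44% and 60%. In the mutant head the recovered shares at 4-, 8- and 16-fold were 28%, 82% and 92% for expression, 28%, 68% and 80% for 3'UTR sites and 8%, 28% and 52% for upstream sites. In the mutant body they were 46%, 86% and 88%, then 18%, 68% and 84%, then 2%, 26% and 40%. Changes of 2-fold were recovered in at most 8%. In the narrower mix of 2-fold and 4-fold changes, 42% of 4-fold expression changes between head and body, 5% in the mutant head and 36% in the mutant body were recovered. For 3'UTR sites these shares were 0%, 28% and 17%, and for upstream sites 5%, 3% and 0%. In the wider mix 2.22% to 6.12% of calls were unchanged genes, and in the narrower one up to 16.7%. The simulated counts had no block or pair structure and random directions of change, so these shares may not hold for the real libraries.

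Replicate numbers come from the labels. Over the 4 wild-type pairs, the deviations of head and body libraries of the same number from their group means correlated at 0.722, 0.711, 0.738 and 0.660 across genes. By a limit of 0.1 fixed for this check, the wild-type numbers were taken to pair the libraries. The fit with the replicate number as a block is given where it moves a result. These values include the difference between blocks, and in block 2 mismatched libraries correlated nearly as well. Head replicate 3 with body replicate 4 had 0.701, and head replicate 4 with body replicate 3 had 0.650. Within blocks the values were 0.633 in block 1 and 0.103 in block 2. A pairing of replicates 3 and 4 is thus not shown. The mutant numbers, with only 2 pairs (0.0326), were not taken as paired.

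Alternatives were other scalings, tools, filters, minor-site and read minimums, the joining window (48 nt), the choice of sites, thinning to the smallest library, each block model and leaving out each library. Added after the data were seen were a joining step without positions under 5 pooled reads, fits within 1 tissue, a fit without the libraries with most transcripts of the other tissue, calls not shared between tissues, list tests with the replicate block, a comparison of block 1 wild type with both genotypes at called genes, a distal share over pairs common to all libraries, and tests of neighbouring sites and single sites without gene names.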

Results

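To describe the tissue difference on which the mutant is set, gene expression was first compared between wild-type heads and bodies (4 libraries each). Photoreceptor genes stood among the genes highest in heads. ninaC, an unconventional myosin with a kinase domain, had 6735 ± 955 CPM (mean ± SD) in heads and 131 ± 139 in bodies (log2 fold change 6.63, SE 1.23, edgeR adjusted p = 0.00173). The rhodopsin chaperone ninaA had 862 ± 491 against 11.2 ± 16.2 (6.58, adjusted p = 0.00303). Arr1, an arrestin, had 41495 ± 37408 against 1978 ± 2312 (6.42, adjusted p = 0.00741), and the homeobox gene Pph13 239 ± 185 against 1.93 ± 2.86 (6.18, adjusted p = 0.00114). bsh, another homeobox gene, had 101.9 ± 48.8 CPM in heads and no reads in bodies, at least 126-fold higher against a floor of 3 counts over the group. Ggamma30A (5.69, adjusted p = 2.6e-04), CG9150 (5.72, adjusted p = 0.00245) and CG10357 (5.43, adjusted p = 5.8e-04) completed the 8 highest.

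Among the genes lowest in heads, 8 had no reads there. CG31709 was at least 79.0-fold, CG33723 70.0-fold, Vha16-5, a proton pump subunit, 61.8-fold, CG5043 55.5-fold, lncRNA:CR44606 52.0-fold, CG32985 51.1-fold, lncRNA:CR43826 46.8-fold and CG13127 44.0-fold lower, each against that floor. Of 2420 genes tested, 1163 were called, 418 higher and 745 lower in heads, with 1277 at an unadjusted p under 0.05.

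Of the gene lists, all 6 neuronal genes tested rose in heads (median log2 fold change 3.48, camera adjusted p = 7.7e-04, 0.324 with an estimated correlation). They included nrv3, a sodium pump subunit (1488 ± 341 against 111 ± 35.9 CPM), VGlut, the vesicular glutamate transporter (670.5 ± 97.5 against 56.8 ± 16.8), and Gad1 (3.18, adjusted p = 4.7e-04). Phototransduction genes rose in 5 of 6 cases (median 6.30, camera adjusted p = 0.0238, 0.356 with an estimated correlation). All 10 genes of the male germline and accessory gland fell (median −6.18, or −5.98 with genes without reads in a group at their bound, camera adjusted p = 1.9e-04, 0.344 with an estimated correlation). Acp26Aa, a seminal fluid protein, had 80.3 ± 66.6 CPM in heads and 5602 ± 1203 in bodies, and Acp62F 9.62 ± 5.96 and 1005 ± 331. The head library of replicate 3 stood apart at Acp26Aa with 179 CPM.

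All 4 gut genes fell, Jon25Bii, a protease, among them (59.6 ± 76.4 against 1031 ± 820 CPM, log2 −4.71), with camera adjusted p = 0.171. Muscle was divided, since TpnC25D, a troponin C, rose (2057 ± 642 against 267 ± 58.4) and 3 genes fell, Mhc (−2.38, adjusted p = 0.00785) and sls (−2.07, adjusted p = 0.00600) among them. Both chemosensory genes rose (Obp28a, an odorant-binding protein, 410 ± 83.3 against 19.0 ± 21.5 CPM, and Ir25a, 2.92). So did both glial genes (Eaat1, 1.89, and nrv2, 2.33) and both detoxification genes (Cyp28d1, 2.19, and Cyp28a5, 1.86). Rises came also in 2 of 3 circadian genes (tim, 1.35, and jet, 0.92), the 1 eye pigment gene (pr, 2.70), 1 of 2 cleavage and polyadenylation genes (Rbp9, 1.09) and 1 of 7 Pol II and elongation genes (Ctr9, 1.28). Adjusted over the list alone, the calls were 6 neuronal, 5 phototransduction, 10 male, 4 gut, 4 muscle, 2 chemosensory, 2 glial, 2 detoxification, 2 circadian, 1 eye pigment and 1 cleavage gene, and 0 for Pol II.

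No call came, by edgeR over all genes or adjusted over the list alone, among 19 ribosomal protein, 6 oxidative phosphorylation, 4 fat body, 2 immune, 2 long-3'UTR, 1 eggshell and 1 heat shock genes. RpL13 (0.66, adjusted p = 0.300), Hsp83 (−0.96, adjusted p = 0.296) and Drs (−0.57, adjusted p = 0.511) are examples. In all, 3 lists passed camera with the preset correlation and 0 with an estimated one (by fry, 6 directional). With the replicate number as a block, 5 lists passed, gut (0.0348) and ribosomal proteins (0.0454) being added, but 0 with an estimated correlation (adjusted p = 0.468 for each of the 5). In that fit 4 ribosomal protein genes, 1 fat body gene, 3 of 7 Pol II genes and 1 of 2 glial genes rose, while 1 heat shock gene and 1 phototransduction gene fell. The blocked adjusted p was 0.0105 in expression: head against body, wild type: RpL13, 0.0293 in expression: head against body, wild type: RpL7-like, 0.0102 in expression: head against body, wild type: Adh, 0.0343 in expression: head against body, wild type: CycK, 0.0430 in expression: head against body, wild type: Hsp83 and 0.0564, no longer passing, in expression: head against body, wild type: nrv2. Scaling by DESeq2 size factors moved the median of all genes from 0.03 to −0.10.

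To ask how tissues differ in 3'UTR length, the use of the distal over the proximal site was compared within genes. chinmo, a BTB zinc finger transcription factor, used the distal site for 100% of reads in heads (upper limit for the proximal site 1.22%) and 14.6 ± 13.02% in bodies (n = 4 each, log2 change 10.83, SE 1.12, adjusted p = 0.00183). Its sites lie 7301 nt apart at 1697396 and 1704697 on 2L. ab, of the same protein class, used it for 97.1 ± 4.29% and 7.93 ± 7.83% (9.23, adjusted p = 0.00143), and Cks30A, a cyclin-dependent kinase subunit, for 98.5 ± 2.62% and 12.6 ± 9.32% (adjusted p = 0.00186). The distal site also rose in CG12605 (100 against 21.1 ± 34.2%, limit for the proximal site in heads 0.926%), side-II (100 against 24.4 ± 29.0%, limit 1.60%), CG12299 (100 against 41.2 ± 35.7%, limit 1.39%) and pigeon (99.7 against 30.6 ± 24.9%). Among the long-3'UTR genes, Hrb27C, an RNA-binding protein, rose from 23.7 ± 5.92% in bodies to 67.8 ± 7.51% in heads (2.86, adjusted p = 0.00425), its sites 4566 nt apart, and brat had 66.7 ± 57.7% and 100% (limit 1.26%) with 17 body reads (adjusted p = 0.153).

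For 3'UTR site choice: head against body, wild type, 155 of 909 genes were called, 154 toward the distal site in heads and 1 toward the proximal, with a median log2 change of 0.94 over all pairs and 257 genes at an unadjusted p under 0.05. The count was 342 with the replicate number as a block, and it fell to 88 and 84 without the head libraries of replicates 3 and 4, and to 80 and 75 without the body libraries of those numbers. It also fell with no accession block as a term and after thinning to the smallest library. The change grew with the distance between sites (Spearman rho 0.375 over 909 genes, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 4e-05; genes are not independent replicates). Of 5 equal sets of genes, the one with the closest sites (29 to 109 nt) had a median of 0.33 with 11 calls. The one with the farthest (530 to 9298 nt) had 2.50 with 61 calls.

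**Figure D1:**
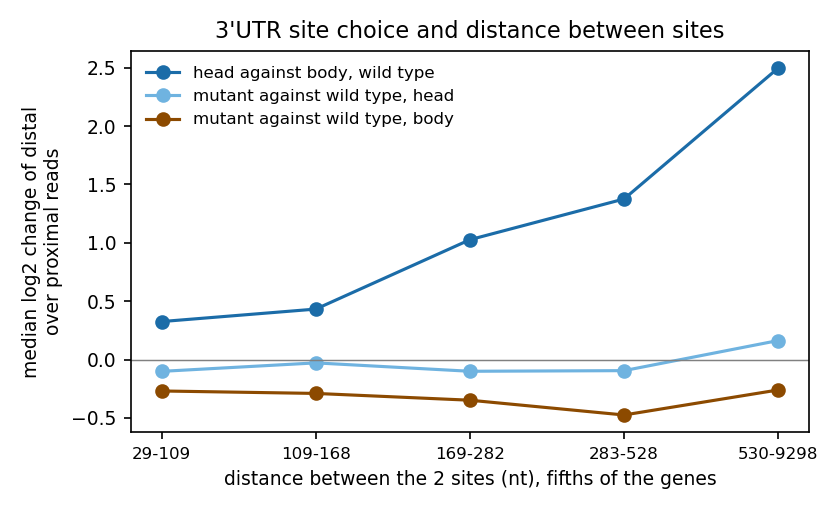
Median log2 change of distal over proximal reads (y) in 5 equal sets of 909 genes by distance between sites in nt (x), for head against body in wild type and for mutant against wild type in each tissue. The tissue change runs from 0.33 to 2.50.

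Per library, the median distal share was 61.8 ± 7.17% in wild-type heads and 38.7 ± 6.31% in bodies, a difference of 23.1 points (n = 4 each, exact permutation p = 0.0286, the smallest for unpaired 4 against 4, adjusted 0.2). This test ignored the blocks and any pairing of the wild-type numbers, and with 4 pairs no exact p under 0.05 is possible. The difference was 26.4 points in block 1 and 19.8 in block 2 (exact p = 0.333 each, the smallest for 2 against 2).

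**Figure D2:**
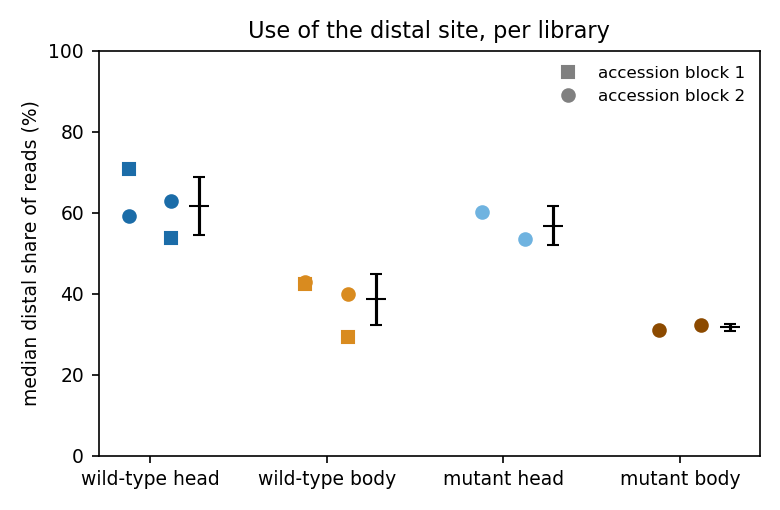
Median share of reads at the distal 3'UTR site in percent (y) for each library by group (x), squares for block 1 and circles for block 2, with bars for mean ± SD. Wild-type heads stood at 61.8% and bodies at 38.7%, mutant heads at 56.8% and bodies at 31.7%.

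Upstream sites were compared between the tissues next. They fell in heads at beat-IIIc (1.95 ± 2.28% of reads against 64.4 ± 30.8% in bodies, adjusted p = 4.2e-05), CG8086 (8.75 against 72.9%, adjusted p = 2.3e-05), promL (16.6 ± 20.2 against 75.8 ± 26.4%, adjusted p = 1.7e-05), dcma (1.13 against 55.3%, adjusted p = 9.4e-05) and haf (1.41 against 47.8%, adjusted p = 0.00121). They rose in heads at CG17217 (96.2 ± 4.64 against 9.38 ± 11.5%, adjusted p = 2.3e-05), Vha68-3, a proton pump subunit (80.2 ± 10.6 against 9.06 ± 8.70%, adjusted p = 5.1e-04), CG18301 (99.0 against 42.8%), CG44139 (54.2 against 0.770%) and Ref2 (79.2 against 1.67%, 11 head reads). Of 910 genes, 92 were called, 22 higher and 70 lower in heads, and 154 with the replicate number as a block. The balance of directions depends on the tool, since limma on log2 ratios called 213 for upstream site use: head against body, wild type, 121 higher and 92 lower. The count was 36 and 38 without the head libraries of replicates 3 and 4, 40 and 38 without the body libraries of those numbers, and 139 without body replicate 2.

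To ask what differs in heads of the slow-polymerase mutant, mutant heads were compared with wild-type heads of the same block (n = 2 each). The Drosomycin-like genes Drsl4 and Drsl5 and a lysozyme rose, while Drs itself had a log2 change of 1.16 (adjusted p = 0.821). Drsl4 went from 9.77 ± 4.19 to 2369 ± 374 CPM (7.98, SE 0.669, adjusted p = 0.00343), Drsl5 from 83.2 ± 18.9 to 1679 ± 109 (4.38, adjusted p = 0.00601) and LysP from 2.34 ± 0.305 to 246 ± 96.2 (6.70, adjusted p = 0.00999). lectin-28C, a C-type lectin, rose from 144 ± 50.4 to 2122 ± 67.2 (3.94, adjusted p = 0.0111) and Iml1, an amino acid sensing regulator of TOR signaling, from 71.8 ± 12.5 to 956 ± 36.5 (3.77, adjusted p = 0.0338). Dci (4.89, adjusted p = 0.00675), CG16743 (4.10, adjusted p = 0.0355) and CG31810 (3.71, adjusted p = 0.0338) rose as well. Acox3, an acyl-CoA oxidase, fell from 818 ± 49.2 to 7.99 ± 0.800 CPM (−6.62, adjusted p = 0.00154), and mthl8, a Methuselah-like receptor, from 214 ± 0.216 to no reads (at least 171-fold lower, adjusted p = 0.00487). CG43149 (at least 55.1-fold lower), asRNA:CR43463 (−5.27), CG9150 (−5.21), CG1275 (−4.32) and CG18301 (−3.08) also fell.

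In all, 20 of 2865 genes were called, 12 higher and 8 lower, with 296 at an unadjusted p under 0.05. Without 1 library the count was 2 (wild-type head replicate 3), 5 (wild-type head replicate 4), 7 (mutant head replicate 1) or 6 (mutant head replicate 2). For expression: mutant against wild type, head, it was 103 by the DESeq2 Wald test, 54 with no low-count filter and 383 in a fit of heads alone, the last chosen after seeing the data. Block 1 wild type, which was outside this test, lay nearer to the mutant at 6 of the 20 genes, such as CG1275, with 8.51 CPM in block 1 wild type, 408 in block 2 wild type and 20.1 in the mutant, where the sign turned with all 12 libraries and a replicate block. At mthl8 it lay with wild type (186 CPM).

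No list held a call over all genes by edgeR in heads, and camera called 0 lists with either correlation. By fry 0 lists were called in a common direction and 1 for changes in any direction (neuronal, adjusted p = 8.3e-05). Adjusted over the list alone, 1 gene each was called in cleavage and polyadenylation and neuronal genes (Rbp9, 1.58, adjusted p over all genes 0.115), eye pigment (pr, −1.19, 0.437), fat body (FASN1, a fatty acid synthase, −1.75, 0.158), gut (Mal-B1, a maltase, −3.03, 0.159) and oxidative phosphorylation (Cyt-c-p, cytochrome c, −2.35, 0.109), and 0 in the other lists. Ribosomal proteins had a median of 0.03, a mean of −0.15 and a test pointing down, and neuronal genes a median of −0.07, a mean of 0.10 and a test pointing up.

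The same comparison in bodies (n = 2 each) moved several of these genes again. LysP rose from 4.61 ± 4.01 to 2351 ± 353 CPM (9.02, SE 0.790, adjusted p = 0.00225) and Drsl4 from 25.7 ± 1.26 to 4958 ± 2040 (7.66, adjusted p = 0.00225). Acox3 fell from 1259 ± 4.35 to 2.89 ± 1.32 (−8.67, adjusted p = 4.6e-04) and mthl8 from 99.5 ± 7.82 to no reads (at least 73.5-fold lower). Spn28Da, a serpin, rose (5.73, adjusted p = 0.00522), with asRNA:CR45738 (7.41), asRNA:CR44897 (5.69), lncRNA:CR44808 (5.58), lncRNA:CR43621 (at least 27.1-fold) and lncRNA:CR43988 (at least 20.4-fold). CG31872 fell from 4371 ± 1624 to 5.61 ± 0.354 (−9.54, adjusted p = 0.00515), Gpo3, a glycerophosphate oxidase, from 706 ± 170 to 11.5 ± 1.06 (−5.89, adjusted p = 0.00225) and Vajk3 from 596 ± 263 to 3.44 ± 4.87 (−7.33, adjusted p = 0.0304). lncRNA:CR43881, lncRNA:CR44490 and CG43149 had no reads in the mutant, at least 19.6-, 14.5- and 11.99-fold lower.

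The count was 65 of 2865 genes, 38 higher and 27 lower, with 483 at an unadjusted p under 0.05. It was 7 without wild-type body replicate 3, 29 without replicate 4 and 908 without mutant body replicate 2. For expression: mutant against wild type, body, it was 213 by the DESeq2 Wald test, 134 with no low-count filter and 31 in a fit of bodies alone, the last chosen after seeing the data. The 2 mutant bodies were not a tight group. Across genes, mutant body replicate 2 correlated at 0.890 with mutant body replicate 1, but at 0.919 and 0.896 with wild-type body replicates 4 and 3. Those 2 wild-type bodies correlated at 0.965 with each other, and the 2 mutant heads at 0.977. Block 1 wild type lay nearer to the mutant at 11 of the 65, Gpo3 among them with 24.3 CPM. Heads and bodies, which share no control library, had 9 higher and 5 lower genes in common, where 0.159 and 0.0754 would be shared by chance (Fisher p = 9.9e-16 and 2.8e-09 across genes, which are not independent replicates). These chance values take the head and body controls as independent, which a possible pairing of the wild-type numbers leaves in doubt.

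Among the lists in bodies, fat body and haemolymph genes had the lowest median, −3.67, over 6 genes (camera adjusted p = 4.6e-04, 0.491 with an estimated correlation), with 0 calls over all genes by edgeR and 5 adjusted over the list alone. Lsp1beta, a larval serum protein, had 7595 ± 9836 and 155 ± 18.4 CPM (−5.64, adjusted p = 0.0895) and Adh 3057 ± 597 and 928 ± 204 (−1.71, adjusted p = 0.0667). Among muscle genes Mhc, the muscle myosin heavy chain, fell from 1010 ± 685 to 114 ± 24.2 (−3.15, adjusted p = 0.0425), the only call of 4, with 2 adjusted over the list alone (camera adjusted p = 0.0217, 0.491 with an estimated correlation). Cyt-c-p fell from 1568 ± 889 to 160 ± 69.0 (−3.31, adjusted p = 0.0317), the only call of 6 oxidative phosphorylation genes over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00857, 0.599 with an estimated correlation), and block 1 wild type had 84.2 CPM, the sign turning with all 12 libraries and a replicate block. Mal-B1 fell from 825 ± 557 to 22.1 ± 17.1 (−5.18, adjusted p = 0.0285), 1 of 4 gut genes either way (camera adjusted p = 0.327). The share of mitochondrial reads was 4.50% and 22.0% in the mutant bodies and 24.2% and 18.3% in the wild-type bodies of that block. Adjusted over the list alone, 1 call each came in immune (TotM, 2.53), chemosensory (Obp28a, 3.04), eye pigment (pr, −1.40) and phototransduction genes (ninaD, −2.58), with 0 over all genes, and 0 in the other lists. By fry 0 lists were called in a common direction and 5 for changes in any direction, fat body (adjusted p = 0.0202), muscle and oxidative phosphorylation (0.0308 each), neuronal (0.0101) and Pol II genes (3.0e-04). Ribosomal proteins (median −0.05, mean 0.03, test down) and phototransduction genes (0.07, −0.35, test down) differed in sign between measures.

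To ask whether 3'UTR sites differ in the mutant, it was compared with wild type in each tissue. Elongation speed was not measured, and any difference between the strains enters this comparison. CG13917 moved to its distal site almost fully, from 44.0 ± 1.45% to 99.96 ± 0.0574% in heads (adjusted p = 2.1e-06) and from 33.8 ± 2.83% to 100% in bodies (limit for the proximal site 0.971%, adjusted p = 2.1e-05), its sites lying at 1599874 and 1600861 on 3L. mxt, a translation factor, moved from 68.3 ± 3.67% to 99.9 ± 0.188% in heads (adjusted p = 5.1e-05), and CG5177 from 69.6 ± 2.21% to 98.7 ± 0.240% (adjusted p = 1.6e-04). In block 1 wild type these 3 genes stood at 100% (344, 113 and 514 head reads), with the mutant, and in heads their sign turned with all 12 libraries and a replicate block. The distal site also rose in heads in Pde11, a phosphodiesterase (82.9 to 99.7%), Nse4 (21.5 to 93.5%), phr6-4, a photolyase (0 to 100%, limits 100% from 3 wild-type reads and 10% from 30 mutant reads) and Dci (0 to 98.5%, limit 75% from 4 wild-type reads). At CG16974 (90.4 to 99.7%) the direction turned with the 48 nt window and with the most distal site against all others.

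Other genes moved to the proximal site. strat fell from 95.9 ± 2.02% to 12.8 ± 1.88% distal in heads (adjusted p = 5.1e-05), CG6729 from 89.3 ± 0.793% to 1.89 ± 0.782% (adjusted p = 5.8e-05) and IA-2, a receptor-type phosphatase, from 76.8 ± 1.63% to 2.34 ± 3.30% (adjusted p = 1.6e-04). CG31717 fell from 52.6 ± 3.63% to 0.682 ± 0.0214% (adjusted p = 4.2e-05) and Lip2, a lipase, from 86.0 ± 10.95% to 0 (upper limit 3.53%, adjusted p = 9.5e-04). The direction at strat turned when positions with under 5 pooled reads were left out, an alternative chosen after seeing the data. ida (77.8% to 0, limit 3.41%, 15 wild-type reads), Nhe1, a sodium-proton exchanger (15.6% to 0, limit 0.683%) and CG16978 (8.20% to 0, limit 0.497%) fell too, the last with its direction turned for the most distal site against all others. At CG6729 (67.7%), Lip2 (77.3%) and IA-2 (94.0%) the wild type of block 1 stood with that of block 2. Of 909 genes, 35 were called, 13 distal and 22 proximal (median −0.03, 110 at an unadjusted p under 0.05), and 18, 14, 17 or 19 without wild-type head replicate 3, 4, mutant head replicate 1 or 2. For 3'UTR site choice: mutant against wild type, head, a fit of heads alone, chosen after seeing the data, called 154. At 8 of the 31 measured, block 1 wild type lay nearer to the mutant, Nse4 among them (63.9% from 36 reads).

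**Figure D3:**
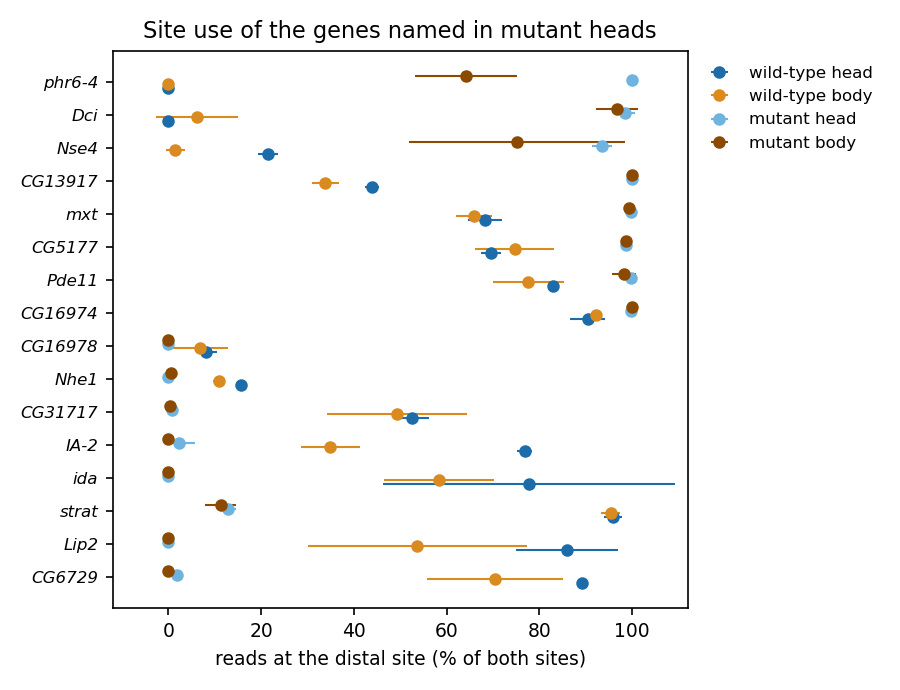
Distal site use in percent in block 2 (mean ± SD, n = 2 libraries per group) for the 16 genes named in mutant heads, in wild-type and mutant heads and bodies. Pde11 goes from 82.9 to 99.7% in heads and IA-2 from 76.8 to 2.34%.

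In bodies the distal site rose in Shaw, a potassium channel (5.36 to 86.6 ± 4.57%, adjusted p = 2.8e-04), CG13989 (64.5 ± 4.6002 to 100%, limit for the proximal site 0.568%), Nse4 (1.47 to 75.2 ± 23.3%), phr6-4 (0, limit 2.31%, to 64.2 ± 11.02%), Dci (6.25 to 96.8%), mxt (66.0 ± 3.85 to 99.4%) and Gpo3 (0.405 to 20.8 ± 17.7%, 21 mutant reads). At Gpo3 the direction turned for the most distal site against all others and with all 12 libraries and a replicate block. It fell in CG14931 (84.1 ± 3.67% to 0, limit 3.0%, adjusted p = 1.5e-04), CG9259 (59.1 ± 19.2% to 0, limit 0.843%), CG5968 (100, limit for the proximal site 5.77%, to 14.3 ± 10.5%), CG1233 (83.5 ± 3.16% to 0, limit 10%), CG6729 (70.4 ± 14.7% to 0, limit 3.45%), ida (58.3% to 0, limit 1.78%), Lip2 (53.7% to 0, limit 1.46%) and Ts, the thymidylate synthase gene (100, limit for the proximal site 42.9%, to 1.57%, 7 wild-type reads), where the direction turned for the most distal site against all others. In all 53 genes were called, 15 distal and 38 proximal, with 158 at an unadjusted p under 0.05, and 12, 11, 98 or 288 without wild-type body replicate 3, 4, mutant body replicate 1 or 2. The count for 3'UTR site choice: mutant against wild type, body, was 30 with at least 50 reads and 34 with the 48 nt window. Block 1 wild type lay nearer to the mutant at 16 of the 48 measured. Named genes among these are CG14931 (35.3%), CG1233 (33.3%), CG13989 (96.3%), Gpo3 (64.3%), CG13917 (100% of 202 reads), CG5177 (100% of 984 reads) and mxt (100% of 126 reads). In CG13917 and mxt the sign turned with all 12 libraries and a replicate block. Total reads of the pair also rose strongly at some genes. From wild type to mutant they went from 7 to 351 at Ts in bodies. At Dci they went from 13 to 89 in bodies and from 4 to 117 in heads. A share there can change with the reads of either site alone, so it does not show a switch of sites. Hrb27C had 18.9 and 7.71 ± 6.78% (adjusted p = 0.286), and in heads 63.8 and 61.2% (adjusted p = 1).

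Heads and bodies had 9 distal and 13 proximal calls in common, where 0.215 and 0.920 would be shared by chance if the head and body controls were independent. The median over all pairs was −0.35 in bodies (95% interval −0.42 to −0.21) and −0.03 in heads (−0.13 to 0.02). The distal share per library differed between mutant and wild type of the block by −4.32 points in heads (exact p = 0.667) and −9.65 in bodies (exact p = 0.333, the smallest for 2 against 2). Over pairs common to all libraries, a measure chosen after seeing the data, it differed by −1.92 points in heads (exact p = 0.667) and −7.74 in bodies (exact p = 0.333). With all 12 libraries the body difference was −6.94 (exact p = 0.4), and wild-type body replicate 2 of block 1, at 29.4%, lay below both mutant bodies (31.1 and 32.3%). Over the common pairs that library stood at 36.4%, above them (32.0 and 33.8%). The correlation of the change with distance was 0.0563 in heads (permutation p = 0.0896, adjusted 0.179) and −0.0206 in bodies (permutation p = 0.536), across genes that are not independent replicates.

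Upstream sites in the mutant were compared last. In heads they rose in Cog8, a Golgi tethering subunit (0, limit 1.28%, to 57.9 ± 1.14%, adjusted p = 1.9e-07), Prp4k, a kinase (2.68 to 47.5 ± 1.22%, adjusted p = 0.0110) and CG32333 (3.56 to 53.1%, adjusted p = 0.0491). They fell in mth, the Methuselah receptor (86.3 to 9.94%, adjusted p = 0.0110), Cpr62Bb, a cuticle protein (32.1 to 0.342%), lectin-28C (9.26 to 0.793%) and Naprt (5.53 to 0.448%). These were the 7 calls of 910 genes, with 56 at an unadjusted p under 0.05, and 1 without any single library of that comparison. For upstream site use: mutant against wild type, head, limma called 3, as did edgeR with at least 50 reads, and a fit of heads alone, chosen after seeing the data, 48. In bodies they rose in Pxn, peroxidasin (1.52 ± 0.822 to 59.6 ± 26.4%, adjusted p = 1.1e-06), mRpL51, a mitochondrial ribosomal protein (0, limit 3.33%, to 73.7 ± 22.6%), Tmtc1 (27.8 to 90.0%), CG31872 (0.0862 to 92.9%, 13 mutant reads) and Acp29AB (0.883 to 70.0%, 7 reads). They fell in Iml1 (42.1 ± 9.03 to 1.48%, adjusted p = 2.1e-05), Rap1, a small GTPase (17.4% to 0, limit 2.56%), CG16985 (5.55% to 0, limit 0.257%), Drsl4 (8.33 to 0.0566%) and Spn28Da (66.7 to 0.289%, 5 wild-type reads). Of 29 calls, 17 rose and 12 fell, and 5, 8, 45 or 171 genes were called without wild-type body replicate 3, 4, mutant body replicate 1 or 2. A fit of bodies alone, chosen after seeing the data, called 15. Total reads also changed strongly at some of these genes. From wild type to mutant they went from 47 to 1353 at Iml1, 60 to 11152 at Drsl4 and 10306 to 13 at CG31872 in bodies. In heads they went from 296 to 5024 at lectin-28C and from 217 to 2353 at Naprt. A share there can change with the 3'UTR reads alone, so it does not show a switch of sites. At 1 of 6 genes in heads (Naprt, 0.523%) and 7 of 28 in bodies, block 1 wild type lay nearer to the mutant. These 7 include, of the genes named above for a fall in bodies, each with at least 10 reads in block 1, namely Iml1 (4.65%), Rap1 (1.89%), CG16985 (0.120%) and Drsl4 (no upstream reads of 165), while Spn28Da had 3 reads. The genes mth and lectin-28C, named above for heads, were also called lower in bodies, and there block 1 wild type (100% and 30.8%) lay nearer to wild type.

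Whether the genotype effect differs between the tissues was tested as an interaction. Pxn was the 1 call for upstream sites (log2 −7.38, SE 1.64, adjusted p = 0.0270), with 1.20 and 0.696% upstream in wild-type and mutant heads. It was the only call of 910 genes, with 42 at an unadjusted p under 0.05 by edgeR, and limma called 0 (63 unadjusted). There were 0 calls without wild-type head replicate 4, wild-type body replicate 3 or 4, or mutant head replicate 1 or 2, and 48 without mutant body replicate 2. For 3'UTR sites edgeR called 0 of 909 genes (37 unadjusted, and limma 0 with 69), with a median difference of 0.21 (0.09 to 0.32), but 11 without mutant body replicate 1 and 115 without mutant body replicate 2.

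For expression edgeR called 0 of 2865 genes (174 unadjusted) and DESeq2 12, and edgeR 308 without mutant body replicate 2. Scaling by DESeq2 size factors moved the median from 0.11 to −0.04. No list was called by camera (lowest adjusted p 0.0630, gut) or by fry in a common direction, and 1 by fry for changes in any direction (neuronal, adjusted p = 0.00610). Adjusted over the list alone 1 gene each was called in immune (TotM, −2.45), chemosensory (Obp28a, −2.64), and cleavage and neuronal genes (Rbp9, 2.14), with 0 over all genes and 0 in the other lists. Ribosomal proteins (median 0.17, mean −0.18, test up) and phototransduction genes (−0.23, 0.17, test up) differed in sign. The correlation of the interaction with distance between sites was 0.0324 (permutation p = 0.328, adjusted 0.437).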

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

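The tests of head RNA in body libraries, of strain sequence, of an earlier site favoured by slow elongation and of mutant body replicate 1 were chosen after their results were seen, as were the pairs of neighbouring sites, the single sites, the comparison of block 1 wild type at called genes and the interval of the distance test in bodies. The others were set before.

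Within groups of 4 libraries, 16 of 146 values lay far from the other 3, where chance gives about 1 in 20 groups (7.3 here), and 14 of the 16 belong to block 1. Wild-type head replicate 1 had 8.33% mitochondrial reads (23.4 to 24.9% in the others), 126 CPM of ninaA (1083 to 1127), 32060 of Adh, 58549 of nrv2 and 3613 of Hsp83. Wild-type head replicate 2 had 22.5% of reads at its most used position (3.04 to 6.09% in the others), 16.3 CPM of Ir25a, 173 of Jon25Bii, 48.9 of CycK and 68.5 of lilli. Wild-type body replicate 2 had 35.3 CPM of ninaA (0.887 to 4.96 in the others), 3428 of RpL13 and 2252 of Jon25Bii, and wild-type body replicate 1 had 11.2 of CG10357. In block 2, wild-type head replicate 3 had 179 CPM of Acp26Aa and 312 of Acp33A.

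The first pattern is that several eye transcripts stood higher in the wild-type body libraries of block 1. As a percent of heads, ninaC was 2.95 and 4.96 in body replicates 1 and 2 but 0.0963 and 0.239 in replicates 3 and 4, ninaA 2.75 and 3.26 against 0.0787 and 0.446, and Arr1 3.401 and 14.5 against 0.112 and 0.168. Pph13, a gene of low counts, was higher in replicate 1 alone (5.40, against 0.422 in replicate 4 and no reads in replicates 2 and 3). Neuronal genes were divided, with nSyb at 7.72 and 12.2 against 2.55 and 4.999 and VGlut at 12.5 and 11.5 against 6.25 and 5.195, but Rbp9 at 25.4 and 21.2 against 81.8 and 55.9, Syt1 at 6.52 and 6.51 against 11.5 and 4.07 and nrv3 at 6.07 and 10.9 against 6.64 and 6.48. Exchanged labels are argued against, since body genes stayed higher in these body libraries than in heads by a median log2 of at least 4.67. Head RNA mixed into the body libraries may contribute. Over 34 genes the middle of the shares spanned 3.00-fold, but the libraries of block 2 spanned 3.01- and 3.59-fold, so this test cannot decide it, and a difference in how the animals were divided stays open as well, untested.

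The second pattern is the set of 36 genes called for 3'UTR sites in mutant heads or bodies that moved the same way in the other tissue at an unadjusted p under 0.05. A sequence difference between the strains outside RpII215 may explain a part, since 63.9% of them had a site under 5% in one genotype, against 26.5% of other genes and 52.3% of genes called between tissues (Fisher p = 0.265 against these), so the test does not separate it from any strong change. Slow elongation that gives more time at the earlier site asks for proximal shifts, and 36.1% moved to the distal site (13 of 36, exact binomial p = 0.132), which leaves it open. The contrasts lie within block 2, so a difference between the blocks does not enter them, and block 1 wild type lay nearer to block 2 wild type at 75% (27 of 36). A batch that follows the genotype within block 2 is confounded with it and stays open. The genotype, the strain and any difference between the wild-type stocks cannot be told apart in this design.

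The third pattern is the shift toward proximal sites in mutant bodies (median log2 −0.35, interval −0.42 to −0.21), although the distal share of wild-type body replicate 2 (29.4%) lay below that of both mutant bodies (31.1 and 32.3%). It was −0.35 (−0.42 to −0.25) without mutant body replicate 1, the library with 4.50% mitochondrial reads, which argues against that library as the only source. Fewer head-like transcripts in the mutant bodies could contribute, as pairs with little tissue difference had a median of −0.12 (−0.35 to 0.09, 167 pairs), too wide to decide. Slower elongation acting more in bodies stays open too, with a correlation of change and distance between sites of −0.0206 (−0.0834 to 0.0461).

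The count of genes that differ between head and body was compared with all 35 splits of the 8 wild-type libraries. For expression only the real split, 1 of 35, gave as many (1163, highest other 408), and so for upstream sites (1 of 35, 92, highest other 41). Every other split puts heads and bodies on the same side, which adds the tissue difference to the spread. Low counts there were thus largely fixed in advance, so the rank of the real split cannot decide about chance. For 3'UTR site choice: head against body, wild type, 2 of 35 splits gave as many, the real one (155) and the split by block (202). Within block 2 the tissue contrast called 323 genes, and with the replicate number as a block 342. The real split was fitted with the accession block as a term, and the block split could not be. With no such term the tissue contrast called far fewer than 155 genes. Among the 8 splits that part all 4 pairs, the highest other count was 0 for expression and 3'UTR sites and 1 for upstream sites. The other splits leave the head and body library of at least 1 number on the same side. If the libraries are paired, the 8 splits that part all pairs are too few for a share under 0.05. The block split points to a structure of the libraries that is not tissue.

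The genotype effect on the upstream sites of Pxn differed between heads and bodies by a test of the interaction (log2 −7.38), where limma called 0 genes. It was the only gene called by edgeR, which called 0 without wild-type head replicate 4, wild-type body replicate 3 or 4, or mutant head replicate 1 or 2, and 48 without mutant body replicate 2. Outside the named regions, 313 of 1621 neighbouring site pairs differed between wild-type heads and bodies, 259 toward the downstream site in heads.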

How the results depend on the processing

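For single genes, 3589 values under the alternatives set before the data were seen kept direction and side of the threshold, 88 passed it newly, 352 no longer passed it and 22 changed sign, and under the alternatives chosen after seeing the data these counts were 195, 16, 10 and 1. Without 1 library at a time, the counts of called genes ran from 952 to 1420 for expression: head against body, wild type. They ran from 2 to 7 for expression: mutant against wild type, head, from 7 to 908 for expression: mutant against wild type, body (908 without mutant body replicate 2) and from 0 to 308 for expression: genotype effect in head minus body. For 3'UTR site choice: head against body, wild type, they ran from 75 to 182, for 3'UTR site choice: mutant against wild type, head, from 14 to 19, for 3'UTR site choice: mutant against wild type, body, from 11 to 288 and for 3'UTR site choice: genotype effect in head minus body from 0 to 115. For upstream site use: head against body, wild type, they ran from 36 to 139, for upstream site use: mutant against wild type, head, 1 to 1, for upstream site use: mutant against wild type, body, 5 to 171 and for upstream site use: genotype effect in head minus body 0 to 48. A lone library in a group is then assumed to vary like the others. With all 12 libraries and a replicate block, the mutant called 730 genes in heads and 802 in bodies for expression, 222 and 287 for 3'UTR sites, and 70 and 113 for upstream sites, and by construction this compares mutants with block 1 wild type. There the sign changed for CG1275 (1.68), brat (2.95), Cyt-c-p (1.82) and santa-maria (3.88) in heads, and in bodies for Rbp9 (1.74), RpL37A (1.71), Gad1 (−1.79), Cyt-c-p (0.74), santa-maria (2.42) and, as expression: mutant against wild type, body: Arr1, −5.96. It also changed for the 3'UTR sites of CG13917 (−0.44) and mxt (−0.29) in heads. For 3'UTR site choice: mutant against wild type, head: CG5177 it was −5.79. For 3'UTR site choice: mutant against wild type, body: CG13917 it was −1.28, 3'UTR site choice: mutant against wild type, body: mxt −1.88 and 3'UTR site choice: mutant against wild type, body: Gpo3 −3.01. With all 12 libraries and no block, the counts in heads and bodies were 2 and 23 for expression, 2 and 4 for 3'UTR sites and 1 and 7 for upstream sites, with 0 for the upstream interaction. With the accession block they were 16 and 28 for 3'UTR sites, 1 and 10 for upstream sites and 0 for the interaction. In the tissue contrast, no accession block gave 26 for 3'UTR sites and 17 for upstream sites, accession block 2 alone 323 and 164, and the replicate block 342 and 154, with 4 for the 3'UTR interaction and 5 gene lists (chosen after seeing the data), and it moved no other count past 1.5 times. Besides RpL13, RpL7-like, Adh, CycK, Hsp83 and nrv2 it changed no other call of a gene named for the tissue contrast. Of the phototransduction genes not named for that contrast, 1 was newly called lower in heads. Other tools gave, by the DESeq2 Wald test, 103 in heads, 213 in bodies and 12 for the expression interaction, and by limma 213 for upstream sites between tissues (121 higher and 92 lower in heads, where edgeR had 22 and 70), 3 in mutant heads and 0 for the interaction. With no low-count filter expression had 54 in heads and 134 in bodies. At least 50 reads gave 30 for 3'UTR sites in bodies, 3 for upstream sites in heads and 0 for the upstream interaction, as did each class at least 5% (0). A joining window of 48 nt gave 34 in bodies, 1 for the 3'UTR interaction and the reverse sign at 3'UTR site choice: mutant against wild type, head: CG16974 (−4.62). The most distal site against all others gave 1 for that interaction and reversed CG16974 (−4.04), CG16978 (5.56), Gpo3 (−6.11) in bodies, and 3'UTR site choice: mutant against wild type, body: Ts (10.94). A minor site of at least 10% gave 1 for it as well. Thinned to the smallest library, 3'UTR sites had 96 between tissues and 34 in mutant bodies, where fewer reads are the cause by construction. Camera with estimated correlation called 0 lists between tissues and 0 in mutant bodies. For expression: mutant against wild type, body: Cyp28a5 the log2 change was −2.24 without mutant body replicate 2 and 1.34 without mutant body replicate 1. Its sign thus depends on which mutant body is left out. Chosen after seeing the data, fits of the tissue alone gave 383 in heads and 31 in bodies for expression, 154 in heads for 3'UTR sites, and 48 and 15 for upstream sites. Calls left after setting aside genes with the same sign at an unadjusted p under 0.05 in the other tissue were 7 and 23 for 3'UTR sites and 2 for upstream sites in heads. With positions under 5 pooled reads left out, 3'UTR site choice: mutant against wild type, head: strat changed sign to 10.54. Except where construction is named, the cause was not tested.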

Other observations

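At a minority of genes called for the mutant, the wild-type libraries of block 1 lay nearer to the mutant than to wild type of block 2, a comparison chosen after seeing the data. For expression these were 6 of 20 genes in heads and 11 of 65 in bodies, for 3'UTR sites 8 of 31 and 16 of 48, and for upstream sites 1 of 6 and 7 of 28. The 3'UTR of CG13989 was used at its distal site for 96.3% of reads in block 1 wild-type bodies, 65.0% in block 2 wild type and 100% in the mutant. Gpo3 used its distal site for 64.3%, 0.364% and 19.0%. For expression in heads, Dci had 45.1 CPM in block 1 wild type, 2.44 in block 2 wild type and 73.4 in the mutant, and CG31810 20.6, 1.38 and 19.8. Other genes stood with wild type, such as Acox3 in heads (277, 818 and 7.99 CPM) and Pxn in bodies (0.354% upstream).

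Sites were also compared one by one over all arms, without gene names, a test chosen after seeing the data. Of 11999 sites tested between wild-type heads and bodies, 5234 were called, 2240 higher and 2994 lower in heads. In the mutant 250 of 12864 were called in heads (93 higher, 157 lower) and 306 in bodies (124 higher, 182 lower), and 1 for the interaction by edgeR (633 at an unadjusted p under 0.05).

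Neighbouring site pairs outside the named regions, the rest of 3L included, had a median log2 change of 0.61 (0.55 to 0.70) between heads and bodies, toward the downstream site in heads. In the mutant the median was 0.04 in heads, with 45 calls, and −0.10 (−0.17 to −0.02) in bodies, with 46. Without wild-type body replicate 3 the body median was −0.05 (−0.12 to 0.01) with 0 calls, and the body calls were 0 without wild-type body replicate 4, 169 without mutant body replicate 1 and 761 without mutant body replicate 2. In the named regions 77.8% of such pairs lay in a single 3'UTR, and this share is not known outside them.

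The first component over 2972 genes held 59.4% of the variance and parted the tissues, and the second held 22.3% and parted the blocks.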
